A study of Homo sapiens with 10 samples.

How the data were processed

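RNA of untreated EndoC-BH1 and EndoC-BH5 cells was sequenced in 10 libraries, 5 per line. Total RNA was isolated with an RNeasy Micro kit and libraries were made with a KAPA mRNA HyperPrep kit, per the labels' protocols. The submitters' processing notes name FastQC, fastp, DRAGEN and Picard, without role or version, and the hg38 genome build. The aligner, the counting program, the strand setting and the annotation release were not given in the sources used here.

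The authors deposited a table of CPM and a table of TPM, per the file headers, each with 1 column per library. The CPM values of each library sum to 1000000 in the deposited table and the TPM values to between 999096 and 999537. The lowest CPM values in a library are multiples of 0.01 of the value of 1 read, as estimated, not whole, counts would give. The most frequent low CPM value of a library was taken as the value of 1 read. The depth recovered from it was 84138200 to 122494000 reads per library in EndoC-BH1 and 81646900 to 101500000 in EndoC-BH5. Within 0.02 of a read, 81.2% to 83.0% of the values above 0 were whole reads, so no count test was run. A count of 0 allows up to 3 reads, or 0.0245 to 0.0367 CPM, which covers counting error only. TPM values depend on transcript length and keep no depth.

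Columns were assigned to a line by their names. The letters in them match no batch number in the labels, so a column is a library of its line without a number. All 20 columns of values were used.

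Genes were kept where CPM was at least 1 in at least 5 of the 10 libraries. The test was limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with a trend in the prior variance, two-sided, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. No covariate was fitted. The design foresaw this test for CPM values. Gene lists, 32 with 800 genes, were fixed before the data were examined, as were the tests, the alternatives and the rule for named genes. The 30 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. fry asks whether the genes of a list move one way on balance, and does not compare the list with other genes. List counts were also adjusted over the list alone. Shares and gene numbers per library were compared by exact two-sided permutation of the 252 arrangements of 5 and 5 libraries.

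The named genes are 22 key genes of the lists, the 12 highest and 12 lowest by log2 fold change, and up to 4 members of each list with the largest change. The highest and lowest were taken among genes with an adjusted p below 0.05, with no overlap between the lines, at least 10 CPM in the higher line and a gene symbol. Genes of the Y chromosome, XIST and TSIX were left out of the named genes. This gave 157 genes. Some genes that these rules take are not reported here. Members of lists that illustrate a direction, and the neighbours and copies of named genes, are named beyond this rule and were chosen after their values were seen.

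Positions came from GENCODE release 29 on GRCh38, matched by symbol, for 14985 of the 15527 tested genes. GRCh38 is the assembly called hg38 in the notes, and no coordinates were converted. Windows of 10 Mb along the autosomes with at least 15 tested genes were compared with 10000 random draws of as many genes, with Benjamini-Hochberg adjustment over 270 windows (Python 3.11.15, numpy 2.4.6, pandas 2.3.3). The windows were chosen after seeing the data. The rules that decide the tests of gene copy number and of TERT were amended, in the case of copy number to a stricter one, after their values were seen, as given with each. Figures were drawn with matplotlib 3.10.9.

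Alternatives were a pseudocount of 0.1 or 0.5, no filter on low values, a filter of 5 CPM, the TPM table, TMM scaling (trimming 30% of log ratios and 5% of mean levels), quantile normalization, no trend in the prior variance, each library left out in turn and, for shares, the top 10 or 200 genes. Fits without EndoC-BH1 libraries D and E, and without A, B and C, were added after seeing the data. So were fits that left out the same libraries and kept the genes tested with all 10, since a filter of 5 libraries drops genes of one line once a library of that line is left out. Biotype counts were repeated with the TPM table, TMM scaling and quantile normalization. The model was tested on simulated data for the comparison of EndoC-BH5 with EndoC-BH1, with 200 of 15362 genes changed. It recovered 64.2% of genes changed by 0.5 on the log2 scale, 100% of those changed by 1 and 100% of those changed by 2, with 11 false calls, 5.88% of all calls. The simulated list was called and no other was. The simulation drew each gene independently, with a dispersion of 0.02 and no sets of libraries within a line. In the list test only the simulated list was changed. It therefore does not show how often camera calls lists falsely where genes vary together.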

Results

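EndoC-BH1 is a human beta cell line made from fetal pancreas with the SV40 large T antigen and a telomerase transgene, and EndoC-BH5 is a later line of the same family. The series compared the RNA expression of both lines without treatment, with 5 libraries per line that the labels call batches. Another part of the series, on stimulation with interferon gamma and interleukin 1 beta, was not analysed here. The authors' table of counts per 1000000 (CPM) gave 36991 genes a value above 0 in at least 1 library. The depth recovered from the CPM value of 1 read was 81646900 to 122494000 reads per library. The columns of the table carry letters, B, C, E, F and G for EndoC-BH5 and A to E for EndoC-BH1, which name the libraries below. Values are given as mean CPM ± SD over the 5 libraries of a line, and fold changes as log2 of EndoC-BH5 to EndoC-BH1 on the scale of log2(CPM + 1), which understates the change of genes with low values.

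Libraries of one line resembled each other more than those of the other line. Pearson's r of log2(CPM + 1), across genes, was 0.988 to 0.996 within EndoC-BH5, 0.974 to 0.997 within EndoC-BH1 and 0.892 to 0.905 between the lines. The first principal component held 82.7% of the variance and separated the lines. The second held 9.62% and set EndoC-BH1 libraries D and E apart from A, B and C. Within each of these EndoC-BH1 sets r was 0.996 to 0.997, and between them it was 0.974 to 0.982. The labels give no batch for a letter, so this split could not be tied to one. No pair of libraries of a line agreed within sampling noise, the lowest chi-square per degree of freedom being 30.8.

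**Figure D1:**
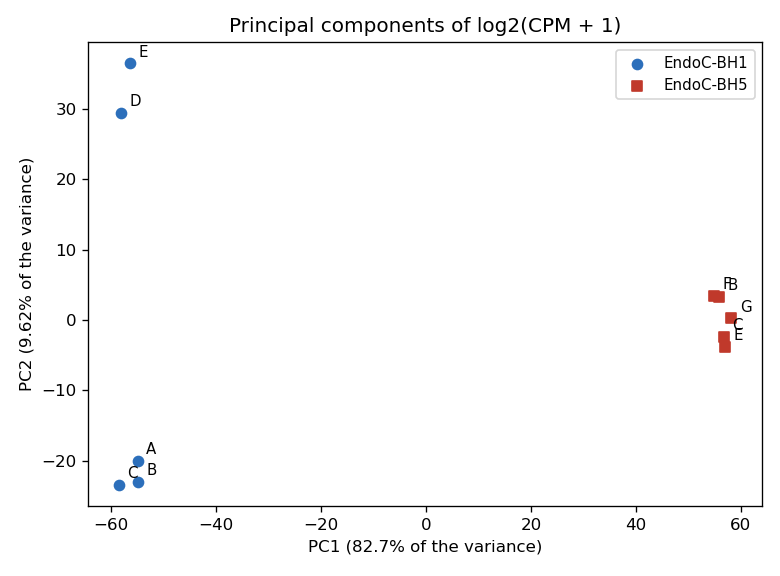
Principal components of log2(CPM + 1) over the tested genes, PC1 on the x axis and PC2 on the y axis, with their share of the variance. Each point is a library, marked by its letter, with circles for EndoC-BH1 and squares for EndoC-BH5. The lines lie at opposite ends of PC1, and EndoC-BH1 libraries D and E lie apart from A, B and C on PC2.

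Most expressed genes differed between the lines. Of 15527 genes with at least 1 CPM in at least 5 libraries, 10812 differed at an adjusted p below 0.05 (limma, Benjamini-Hochberg), with 4834 higher and 5978 lower in EndoC-BH5. At least 2-fold differences were found for 2776 genes, 1640 higher and 1136 lower, but 1404 higher and 1440 lower with the authors' TPM table, so that the majority depended on the table. In 8891 genes, or 57.3% of those tested, the 5 values of one line lay wholly above those of the other, where chance gives 0.794%. The median log2 fold change of all tested genes was -0.07. Without EndoC-BH1 libraries D and E the count was 11137 genes, and without A, B and C it was 10459. Nothing in the labels beyond the word batch says how separately the cultures were grown, so the p-values measure the spread between these libraries, which may be partly technical.

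The 12 genes that rose most in EndoC-BH5 had low values in EndoC-BH1, at most 4.47 CPM in the mean. ADA2, which encodes a secreted adenosine deaminase (chromosome 22, 17178790 to 17258235 in GRCh38), rose from 0.0135 ± 0.0189 to 132 ± 7.52 CPM (log2 fold change 7.03 ± 0.0649 SE, adjusted p = 1.19e-14). MSN, which encodes the membrane and cytoskeleton linker moesin, was listed at 0 in all 5 EndoC-BH1 libraries and stood at 98.8 ± 22.0 CPM in EndoC-BH5, at least 2770-fold higher against a floor of 3 reads per library. BASP1, a growth cone protein, rose from 0.682 ± 0.134 to 154 ± 44.9 CPM. ESR1, the estrogen receptor alpha, rose from 0.108 ± 0.0717 to 57.7 ± 12.3 CPM. NPY, the gene of neuropeptide Y, rose from 2.56 ± 2.17 to 145 ± 68.3 CPM, and NEFL, the neurofilament light chain, from 4.47 ± 2.34 to 153 ± 57.5 CPM. TMEM130, EPB41L4A, ANOS1, TPTEP1, GRB10 and EFS completed the 12 highest, with log2 fold changes of 5.85, 5.45, 5.32, 5.26, 4.95 and 4.83.

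The 12 genes that fell most included a homeobox gene, a bone morphogenetic protein gene and 3 MAGE genes. NKX6-3, the homeobox gene (chromosome 8, 41645178 to 41650669), fell from 266 ± 24.4 to 0.0327 ± 0.0318 CPM (log2 fold change -8.01 ± 0.0736 SE, adjusted p = 1.19e-14). The claudin gene CLDN18 fell from 226 ± 45.6 to 0.520 ± 0.294 CPM, and NNAT, the imprinted gene of neuronatin, from 119.97 ± 14.3 to 0.334 ± 0.584 CPM. BMP5 fell from 94.8 ± 21.4 to 0.0124 ± 0.00834 CPM. The Wnt antagonist SFRP1 fell from 78.9 ± 7.83 to 0.461 ± 0.438 CPM, and the phosphatase inhibitor PPP1R1A from 131 ± 53.3 to 1.07 ± 0.684 CPM. MAGEA3, MAGEA6 and MAGEA12 had log2 fold changes of -6.35, -6.26 and -5.12. MAGEA3 and MAGEA6 are near-identical copies whose reads can be exchanged, so their separate values are uncertain. ZPLD1 and PAX8-AS1 had log2 fold changes of -5.40 and -4.94. PAX8-AS1 overlaps PAX8 on the other strand and the strand used for counting was not given, so the 2 could not be told apart. PAX8 itself stood at 4.17 ± 0.230 CPM in EndoC-BH1 and 0.607 ± 0.0955 CPM in EndoC-BH5. MTND1P23, a nuclear copy of part of a mitochondrial gene, had a log2 fold change of -7.19 and shares sequence with MT-ND1.

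Hormone and secretory granule genes were mostly higher in EndoC-BH5. Of 21 tested members, 15 rose and 3 fell, a shift beyond that of other genes by camera with a preset correlation of 0.01 (adjusted p = 0.00270, or adjusted p = 0.468 with an estimated correlation). INS, which encodes insulin (chromosome 11, 2159779 to 2161341), rose 2.12-fold, from 2728 ± 444 to 5780.1 ± 595 CPM (adjusted p = 1.27e-05, limma). It overlaps the INS-IGF2 read-through gene, which stood at 0.873 ± 0.517 CPM in EndoC-BH1 and 2.05 ± 0.764 CPM in EndoC-BH5. IAPP, the gene of islet amyloid polypeptide that is secreted with insulin, rose from 358 ± 268 to 5382 ± 1232 CPM. Without EndoC-BH1 library C its log2 fold change was 3.77 in place of 4.42, without D and E it was 5.33, and with only D and E for EndoC-BH1 3.06. UCN3, a hormone of mature beta cells, rose from 13.98 ± 2.14 to 128 ± 27.3 CPM, and SCG5, a chaperone of prohormone convertase 2, from 192 ± 52.4 to 761 ± 112 CPM. PCSK1, a proinsulin-processing protease, rose 1.47-fold, but with only D and E for EndoC-BH1 its adjusted p was 0.0972 (3.67e-05 to 0.0993 over its alternatives). PCSK2, PTPRN2 and ERO1B fell, with log2 fold changes of -0.41, -0.41 and -0.37. Within EndoC-BH1, 16 of these 21 genes were higher in libraries D and E than in A, B and C without overlap, by a list median of 0.47 on the log2 scale.

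Genes of the exocytosis machinery also rose. Of 26 members, 17 rose and 1, VAMP3, fell, or 16 and 1 adjusted over the list alone (camera, adjusted p = 0.00484, with adjusted p = 0.435 with an estimated correlation). The largest rises were in SYT5 (3.49-fold), SYT9 (2.74-fold), VAMP2 (2.53-fold) and RAB3A (2.47-fold), genes of calcium sensors, a vesicle fusion protein and a vesicle GTPase. Of the genes whose products are antigens of islet autoimmunity, 9 of 12 rose and 2 fell (camera, adjusted p = 0.0282, with adjusted p = 0.435 with an estimated correlation). Of the 12, 6 also stand in the granule list. PTPRN rose from 303 ± 42.4 to 860.1 ± 133 CPM, G6PC2 from 53.6 ± 28.7 to 164 ± 59.2 CPM and GAD1 from 0.489 ± 0.0474 to 5.57 ± 2.93 CPM. With only D and E for EndoC-BH1, the adjusted p of each of these 2 lists became 0.0534 with the filter asking for 5 of the remaining libraries, and 0.0435 for both with the genes of all 10 libraries tested (0.00106 to 0.435 over its camera alternatives and 1.20e-05 by fry for exocytosis, 0.00846 to 0.435 over its camera alternatives and 1.28e-05 by fry for the antigens). HSPD1 and PTPRN2 were the members that fell. The log2 fold change of SYT9 was 0.94 against A, B and C and 2.28 against D and E, and that of G6PC2 was 1.06 against D and E in place of 1.69.

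**Figure D2:**
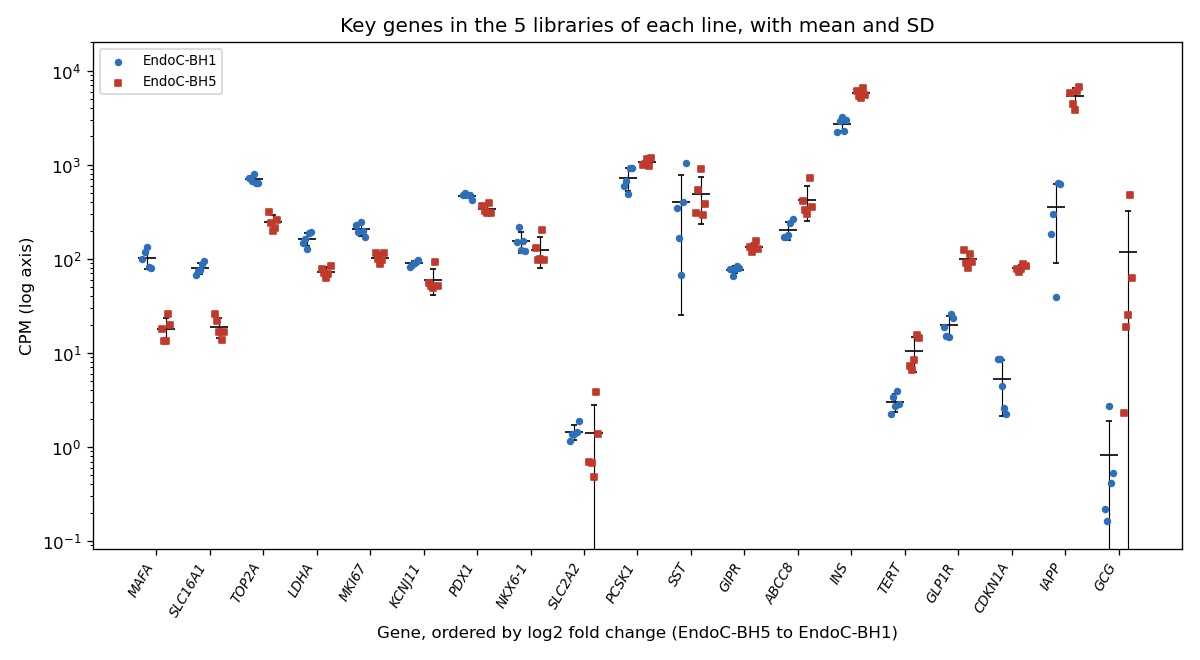
CPM of key genes fixed in advance, on a log axis, in the 5 libraries of EndoC-BH1 (circles) and of EndoC-BH5 (squares). Horizontal marks are means and bars are SD, running off the lower edge of the plot for GCG in both lines and SLC2A2 in EndoC-BH5. Genes are ordered by log2 fold change, from MAFA at -2.46 to GCG at 4.43, and GCG in EndoC-BH5 spreads from 2.31 to 479 CPM.

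Several beta cell transcription factors were lower in EndoC-BH5. MAFA, a regulator of insulin transcription in mature beta cells, fell 5.69-fold, from 103 ± 23.9 to 18.04 ± 5.20 CPM (adjusted p = 6.95e-07, limma). PDX1 fell from 471 ± 32.4 to 339 ± 36.1 CPM, NKX2-2 from 168 ± 6.72 to 76.1 ± 8.73 CPM and MEIS2 from 704 ± 107 to 275 ± 25.1 CPM. FEV, a factor of serotonergic neurons, rose from 3.94 ± 0.994 to 15.1 ± 4.34 CPM. In all, 14 of 26 members fell and 5 rose, and camera did not call the list in the main test (adjusted p = 0.152). The list did pass the threshold in some alternative (camera, adjusted p 0.0131 to 0.468 over its alternatives, and 1.20e-05 by fry). NKX6-1 stood at 153 ± 38.1 CPM in EndoC-BH1 and 125 ± 44.9 CPM in EndoC-BH5 (adjusted p = 0.199). Without EndoC-BH5 library F the fold change of NKX6-1 was -0.51 with an adjusted p of 0.0186 (0.0181 to 0.526 over its alternatives).

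Genes of glucose sensing and excitability went both ways, with 12 of 27 higher and 7 lower (camera, adjusted p = 0.416). The subunit genes of the ATP-sensitive potassium channel moved apart, with KCNJ11 lower (89.6 ± 5.48 CPM in EndoC-BH1 and 59.99 ± 18.2 CPM in EndoC-BH5) and ABCC8 higher (204 ± 43.7 CPM in EndoC-BH1 and 427 ± 172 CPM in EndoC-BH5). With only D and E for EndoC-BH1 the adjusted p of ABCC8 was 0.0565 (8.51e-04 to 0.0586 over its alternatives). The potassium channel gene KCNMA1 rose 3.15-fold, and the sodium channel gene SCN3A rose 3.89-fold. SLC2A2, a glucose transporter gene, was low in both lines at 1.45 ± 0.260 CPM in EndoC-BH1 and 1.41 ± 1.39 CPM in EndoC-BH5 (adjusted p = 0.606). Without EndoC-BH5 library F its fold change was -0.45 (adjusted p = 0.0154, with 0.0142 to 0.936 over its alternatives).

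Among receptors that tune insulin secretion, 12 of 24 rose and 9 fell (camera, adjusted p = 0.340). GLP1R, the receptor of the incretin GLP-1, rose 5.10-fold, from 19.6 ± 5.00 to 100.1 ± 18.01 CPM (adjusted p = 3.42e-07, limma). GIPR, the receptor of the incretin GIP, rose from 77.0 ± 7.11 to 134 ± 13.8 CPM. GCGR, the glucagon receptor gene, rose from 0.256 ± 0.244 to 17.0 ± 3.39 CPM. The adenylate cyclase genes ADCY5 and ADCY8 moved apart, by 2.10 and -3.29 on the log2 scale. Of 14 genes that mature beta cells keep low, 5 rose and 7 fell (camera, adjusted p = 0.857). SLC16A1, a lactate transporter gene, fell 4.22-fold to 18.9 ± 4.68 CPM and LDHA, of lactate dehydrogenase, 2.25-fold to 72.7 ± 8.38 CPM. OAT and REST rose 2.60-fold and 3.47-fold. The median of this list was 0.07 and its mean was -0.10, so that they differ in sign.

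Every tested gene of the mitotic and DNA replication lists was lower in EndoC-BH5. All 36 mitotic genes fell, each at least 2-fold on the log2(CPM + 1) scale, with a median log2 fold change of -1.42 (camera, adjusted p = 3.38e-11, with adjusted p = 0.468 with an estimated correlation). All 41 replication genes fell, 33 of them at least 2-fold, with a median of -1.44 (camera, adjusted p = 2.43e-13, with adjusted p = 0.466 with an estimated correlation). MKI67, the proliferation marker, fell 2.02-fold, from 207 ± 30.5 to 103 ± 11.5 CPM, and TOP2A fell 2.84-fold, from 698 ± 66.7 to 245 ± 46.3 CPM. CENPE and NDC80, of the kinetochore, fell 4.53-fold and 4.37-fold. RRM2, of deoxynucleotide synthesis, fell from 536 ± 80.1 to 139.9 ± 34.0 CPM. Within EndoC-BH1, 22 of the 36 mitotic and 29 of the 41 replication genes were lower in libraries D and E than in A, B and C without overlap, by list medians of -0.17 and -0.14.

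Targets of p53 were mostly higher. CDKN1A, which encodes the cell cycle inhibitor p21, rose 15.2-fold, from 5.30 ± 3.15 to 80.4 ± 5.95 CPM (adjusted p = 4.86e-07, limma). TNFRSF10B, a death receptor gene, rose from 0.262 ± 0.0957 to 7.38 ± 1.24 CPM, PHLDA3 from 0.0933 ± 0.0697 to 5.71 ± 0.794 CPM and SPATA18 from 0.203 ± 0.0890 to 5.06 ± 0.255 CPM. In all, 15 of 26 rose and 3 fell (camera, adjusted p = 0.00217, with adjusted p = 0.298 with an estimated correlation). The 3 that fell were POLH, PPM1D and XPC, and MDM2 and BAX were among the 8 not called. With EndoC-BH5 library B, E, F or G left out and the filter still asking for 5 libraries, the list was not called, with adjusted p values of 0.0678, 0.0677, 0.0781 and 0.0549 (1.23e-04 to 0.298 over its camera alternatives and 4.97e-08 by fry). With the genes of all 10 libraries tested it was called without each library in turn, at an adjusted p of at most 0.00376. Of 14 cell cycle regulators in the list of CDK inhibitors and D cyclins, 2 rose and 7 fell (camera, adjusted p = 0.402). CDK6 fell from 13.95 ± 6.59 to 1.05 ± 0.355 CPM and CDKN2C from 212 ± 21.7 to 96.8 ± 9.17 CPM. TERT, the telomerase gene, rose from 3.03 ± 0.658 to 10.4 ± 4.21 CPM (adjusted p = 1.54e-04, limma). EndoC-BH1 was made with a telomerase transgene, and reads of the gene and of a transgene were not told apart here in either line.

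Markers of other endocrine cells were higher in part. Of 13 alpha cell markers, 9 rose and 1 fell (camera, adjusted p = 0.0278, with adjusted p = 0.467 with an estimated correlation). GCG, the glucagon gene, stood at 0.813 ± 1.08 CPM in EndoC-BH1 and 118 ± 203 CPM in EndoC-BH5, where library F held 479 CPM. Its log2 fold change was 4.43, or 3.49 without library F and 5.28 without library B, and the list lost its call without F (adjusted p = 0.0723, or 0.0518 with the genes of all 10 libraries tested). TTR, which encodes transthyretin, rose from 653 ± 137 to 2935 ± 284 CPM, and GC, of the vitamin D binding protein, from 41.4 ± 15.3 to 249 ± 81.3 CPM. With only D and E for EndoC-BH1 the list's adjusted p was 0.0534, or 0.0470 with the genes of all 10 libraries tested, and with the filter of 5 CPM 0.0745 (0.00685 to 0.467 over its camera alternatives and 1.74e-05 by fry). Of 10 markers of delta, gamma and epsilon cells, 3 rose and 3 fell (camera, adjusted p = 0.805). SST, of somatostatin, varied widely at 406 ± 380.4 CPM in EndoC-BH1 and 484 ± 252 CPM in EndoC-BH5 (adjusted p = 0.355). Against EndoC-BH1 libraries A, B and C alone SST was higher by 1.48 on the log2 scale (adjusted p = 0.0209, with 0.0209 to 0.789 over its alternatives), and against D and E alone the sign turned, at -0.55. GHRL, of ghrelin, rose from 0.243 ± 0.114 to 5.503 ± 3.56 CPM. PPY was not tested, at 0.106 CPM in EndoC-BH5.

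Neuronal and enterochromaffin genes were mostly higher, with 14 of 23 up and 3 down (camera, adjusted p = 0.00470, with adjusted p = 0.344 with an estimated correlation). NEFM, the neurofilament medium chain, rose 20.2-fold, from 36.7 ± 16.8 to 742 ± 240.1 CPM. TPH1, of serotonin synthesis, rose 8.04-fold and TH, of catecholamine synthesis, 15.5-fold, to 55.9 ± 20.5 and 10.4 ± 6.46 CPM. The synaptic vesicle gene SYP fell, with a log2 fold change of -0.74. Markers of non-endocrine cells showed no common direction. Of 11 ductal markers, 5 rose and 2 fell (camera, adjusted p = 0.214, but 0.0372 without EndoC-BH1 library B and 0.154 there with the genes of all 10 libraries tested, with 0.0372 to 0.688 over its camera alternatives and 3.13e-04 by fry), with SLC4A4 at 1.71 ± 0.514 CPM in EndoC-BH1 and 8.51 ± 2.89 CPM in EndoC-BH5 and TFF3 at 3.52 ± 1.82 CPM in EndoC-BH1 and 0.460 ± 0.240 CPM in EndoC-BH5. Of 13 mesenchymal markers, 6 rose and 6 fell (camera, adjusted p = 0.671), with THY1 up to 8.15 ± 1.60 CPM and FN1 down to 5.26 ± 2.02 CPM. The median of this list was 0.22 and its mean was -0.01. Only 3 of 25 acinar markers and 3 of 20 endothelial and immune markers were expressed enough to be tested. Of the acinar ones, CEL and BHLHA15 rose and CPA1 fell, none above 13.2 CPM in the mean of a line. BHLHA15 lost its call with quantile normalization (adjusted p = 0.119, with 0.00107 to 0.119 over its alternatives), and with only D and E for EndoC-BH1 both BHLHA15 and CPA1 lost theirs. Of the endothelial and immune markers ESAM fell to 1.41 ± 0.226 CPM and the others were not called, with an adjusted p of 0.0979 for ESAM with only D and E for EndoC-BH1 (1.47e-04 to 0.0979 over its alternatives), and a median of 0.11 and a mean of -0.08 for the list. Of 16 progenitor and fetal genes, 3 rose and 6 fell (camera, adjusted p = 0.676), with SOX4 down 4.99-fold and the imprinted gene PEG3 down 25.9-fold.

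Interferon-stimulated genes were higher at low levels. Of 18 tested members, 10 rose and 2 fell, among them CD274 (camera, adjusted p = 0.00773, with adjusted p = 0.435 with an estimated correlation). UBE2L6, of the ISG15 conjugation pathway, rose from 0.00775 ± 0.0126 to 3.06 ± 0.630 CPM, ISG15 itself from 0.185 ± 0.0427 to 2.00 ± 0.324 CPM and the antiviral gene MX1 from 1.14 ± 0.305 to 5.68 ± 0.970 CPM. With no filter on low values the list lost its call (adjusted p = 0.134, with 0.00576 to 0.435 over its camera alternatives and 7.06e-06 by fry). Of 19 genes of HLA class I and antigen processing, 10 rose and 4 fell (camera, adjusted p = 0.0818). HLA-C fell to 15.6 ± 3.59 CPM. Reads of these highly variable genes can be lost or exchanged between them where an allele differs from the reference, so their values are uncertain. The list passed the threshold when EndoC-BH1 library B or EndoC-BH5 library C, E or G was left out, with adjusted p values of 0.0297, 0.0435, 0.0331 and 0.0447 (0.0236 to 0.654 over its camera alternatives and 7.97e-04 by fry). With the genes of all 10 libraries tested it did so only without EndoC-BH1 library B, at 0.0236. Of 24 cytokine receptor and NF-kB genes, 10 rose and 7 fell (camera, adjusted p = 0.671), with a list median of 0.08 and a mean of -0.07. The TNF receptor gene TNFRSF1A fell from 6.68 ± 1.20 to 0.277 ± 0.122 CPM. The interleukin 1 receptor gene IL1R1 fell, with a log2 fold change of -0.67, and the interferon gamma receptor genes IFNGR1 and IFNGR2 rose by 0.39 and 0.81.

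Genes encoded by mitochondrial DNA were higher, and nuclear genes of oxidative phosphorylation went both ways. Of 13 mitochondrially encoded genes, 12 rose and MT-ND1 was not called (camera, adjusted p = 4.74e-04, with adjusted p = 0.488 with an estimated correlation). MT-ND5 rose 2.51-fold and MT-CO3 2.66-fold, to 10961 ± 972 and 10471 ± 1257 CPM. With quantile normalization these fold changes were 0.51 and 0.69 on the log2 scale and the list lost its call (adjusted p = 0.0621, with 7.46e-06 to 0.488 over its camera alternatives and 8.92e-05 by fry). Of the nuclear copies that share sequence with MT-ND1 and MT-CO1, MTCO1P12 took 12.6% of its sum with MT-CO1 in EndoC-BH1 and 0.562% in EndoC-BH5, so the levels of both mitochondrial genes are uncertain. All 13 were higher in EndoC-BH1 libraries D and E than in A, B and C, by a median of 0.39. Of 42 nuclear genes of oxidative phosphorylation, 9 rose and 18 fell (camera, adjusted p = 0.519), with NDUFV2 at -1.13 on the log2 scale. Genes of cholesterol synthesis and uptake fell, 17 of 23 with 1, IDI1, higher (camera, adjusted p = 0.00484, with adjusted p = 0.654 with an estimated correlation). EBP, a sterol isomerase gene, fell 5.02-fold and INSIG1 3.12-fold, to 44.4 ± 7.05 and 230.5 ± 39.7 CPM.

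The remaining lists were not called by camera in the main test. Glycolysis genes were split, with 7 of 19 higher and 7 lower (adjusted p = 0.808), PFKP up 4.02-fold. Hypoxia genes had 6 of 15 higher and 5 lower (adjusted p = 0.671), with NDRG1 up 7.17-fold to 95.3 ± 16.7 CPM, a list median of -0.11 and a mean of 0.29. Of 28 genes of the unfolded protein response, 3 rose and 10 fell (adjusted p = 0.6001), or 3 and 9 adjusted over the list alone, with PDIA4 down 2.38-fold and DNAJC3 up 3.11-fold. TXNIP fell to 5.44 ± 5.54 CPM, with an adjusted p of 0.0107 that became 0.213 with only D and E for EndoC-BH1. Immediate early genes had 5 of 21 higher and 8 lower (adjusted p = 0.923), MYC falling from 3.76 ± 2.09 to 0.442 ± 0.367 CPM. Matrix and adhesion genes had 9 of 20 higher and 8 lower (adjusted p = 0.806), with COL4A2 down from 41.3 ± 22.96 to 0.848 ± 0.328 CPM, ITGA1 up 4.29-fold, a list median of -0.05 and a mean of 0.03. Of 52 ribosomal protein genes, 20 rose and 8 fell (adjusted p = 0.214), or 19 and 8 adjusted over the list alone, with RPL3 up 2.22-fold. This list was called in some alternative (adjusted p 0.00194 to 0.879 over its camera alternatives, and 0.151 by fry). Of 15 commonly used reference genes, 1, B2M, rose and 10 fell (adjusted p = 0.112), with TFRC at -1.67 on the log2 scale. The reference list too was called in some alternative (adjusted p 0.00497 to 0.468 over its camera alternatives, and 1.77e-05 by fry).

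**Figure D3:**
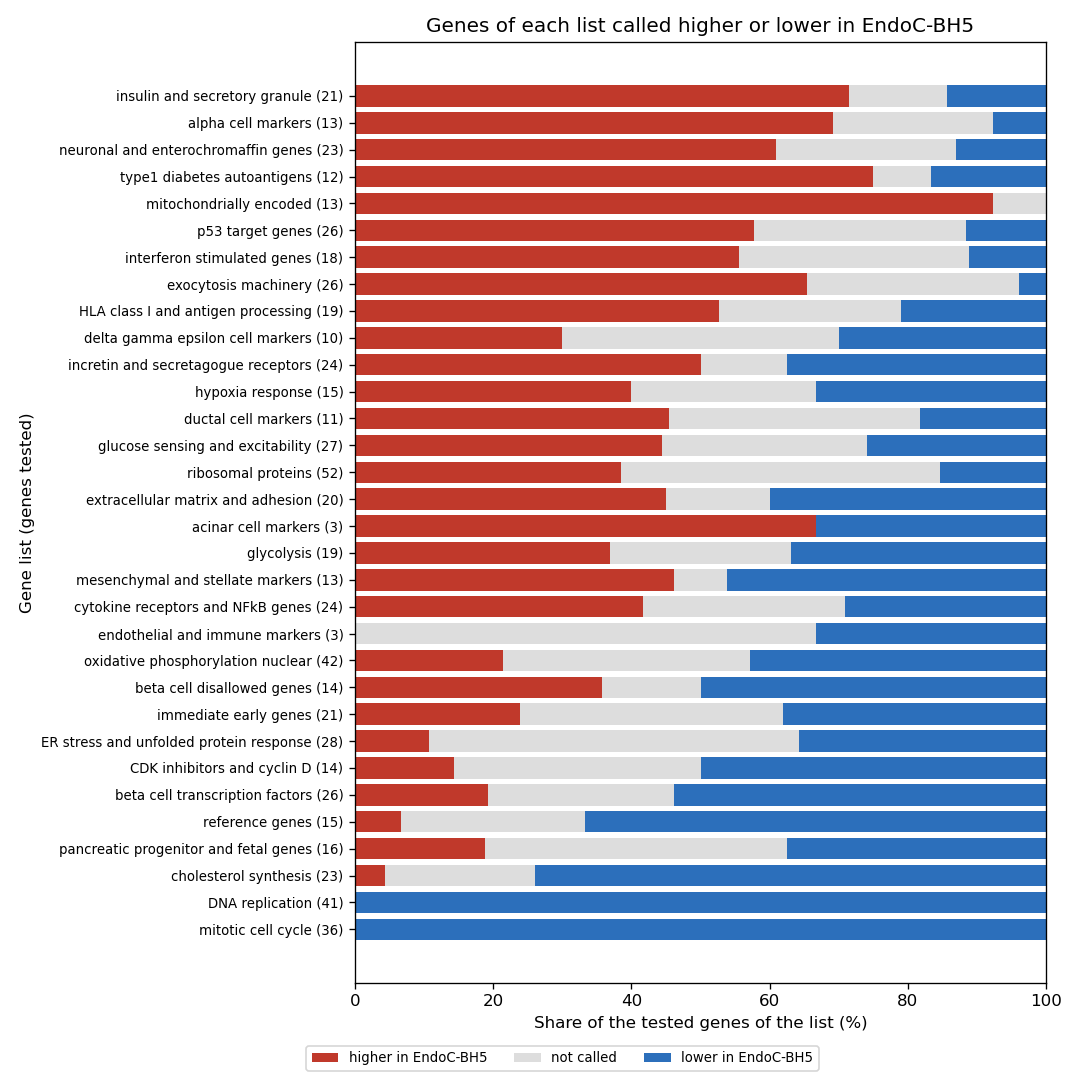
Share of the tested genes of each list, in percent on the x axis, that were called higher (left, red), not called (middle, grey) or called lower (right, blue) in EndoC-BH5 at an adjusted p below 0.05 (limma). Lists are ordered by mean log2 fold change and the number of genes tested is in brackets. All 36 mitotic and all 41 replication genes were lower, and 12 of 13 mitochondrially encoded genes were higher.

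By camera with the preset correlation, 11 of the 30 lists with at least 5 tested genes were called, 8 higher and 3 lower. None was called with an estimated correlation, and 31 of 100 splits of the 10 libraries into 5 and 5 gave as many lists. All splits but the real one mix the lines unevenly, so part of the line difference may count in them. Adjusted over the list alone, the counts of genes called were those given over all genes except where stated, and in hypoxia genes 6 were lower in place of 5.

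Library composition differed as well. EndoC-BH5 libraries held 15321 ± 76.8 genes at 1 CPM or more against 14949 ± 74.5 in EndoC-BH1 (exact two-sided permutation test, p = 0.00794, n = 5 per line, the smallest p that 5 against 5 allows, adjusted p = 0.0106 over 4 measures). The 50 most abundant genes took 20.1 ± 0.638% of the CPM in EndoC-BH5 and 14.3 ± 0.777% in EndoC-BH1 (exact permutation test, p = 0.00794, adjusted p = 0.0106). Mitochondrially encoded genes took 9.53 ± 0.495% and 5.46 ± 0.838% (exact permutation test, p = 0.00794, adjusted p = 0.0106). Ribosomal protein genes took 1.87 ± 0.0730% and 1.68 ± 0.0844% (exact permutation test, p = 0.0159, adjusted p = 0.0159), a difference that reversed in the authors' TPM table, which counts transcripts scaled for length, at -0.0204 percentage points, and lost its call without EndoC-BH1 libraries D and E (exact permutation p = 0.0536). Of the 152 named genes that were called, 144 had no overlap between the lines. Of all named genes, 25 lie in 10 Mb segments of the genome where neighbouring genes moved together, 19 of them in the direction of the segment. These segments hold 7.91% of the tested autosomal genes, and a median of 84.5% of the genes in a segment moved in its direction. Among the 19 are BASP1, NPY, UCN3, PFKP, DNAJC3, NKX6-3, SFRP1, NDC80 and INSIG1. All of those listed changed by more than their segment, from DNAJC3 at 1.65 against 1.36 to NKX6-3 at -8.01 against -0.49 on the log2 scale. ATP5F1C, also among the 19, changed by less than its segment, at 0.69 against 0.83. The segment of NKX6-3 and SFRP1 was not called after a trend on GC content and length was removed (adjusted p = 0.0548). MKI67, TMEM130, BHLHA15, PEG10, COL4A1 and COL4A2 moved against their segment.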

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

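The test of a separate batch was chosen after the result was seen. Values were singled out where 1 library of a line lay far from the other 4 for its range. Of 268 such comparisons, 10 stood out, fewer than the 1 in 20 that chance gives where the 5 libraries of a line vary alike. EndoC-BH1 libraries D and E stand apart from A, B and C, so this count does not show whether the values arose by chance. EndoC-BH5 library F held 6 of the 10.

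In library F of EndoC-BH5, 3 genes were high. KCNJ11 stood at 92.3 against 48.8 to 55.8 CPM, ADCY8 at 5.56 against 1.29 to 1.89 CPM and POU3F1 at 41.8 against 5.60 to 9.78 CPM. In the same library ATP5F1C was low at 92.6 against 109 to 116 CPM, RPL12 at 294 against 331 to 345 CPM and RPL38 at 149 against 198 to 216 CPM. MT-ND3 stood at 1259.6 CPM in EndoC-BH5 library B against 941 to 1011 CPM in the others. In EndoC-BH1 library B, GIPR was low at 64.9 against 78.1 to 83.6 CPM and CD74 high at 110.5 against 48.1 to 54.5 CPM. NDUFB10 stood at 41.4 CPM in EndoC-BH1 library D against 46.7 to 48.5 CPM.

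EndoC-BH1 libraries D and E differed from A, B and C. Of 9721 genes with at least 1000 reads in every EndoC-BH1 library, 192 were at least 2-fold apart without overlap, 77 higher and 115 lower in D and E, which argues against lower depth of D and E as the reason. The mean of IGF2 was 3912 CPM in A, B and C and 1020.4 CPM in D and E, and that of H19 was 95.5 and 6.94 CPM. SST stood at 194 and 723 CPM and PTGS2 at 337 and 1063 CPM. Genes of EndoC-BH5 that A, B and C lack were no higher in D and E, with a median difference of 0% of the EndoC-BH5 level over 21 genes, which argues against EndoC-BH5 cells or RNA in libraries D and E. A separate culture or library batch stays open, since 0 labels give the batch of a letter, and no biological explanation was tested.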

How the results depend on the processing

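Fits without EndoC-BH1 libraries D and E, or without A, B and C, and all fits that kept the genes tested with all 10 libraries, were chosen after seeing the data. The count of differing genes stayed within 1.5 times 10812 under every alternative, from 9825 to 10550 with 1 library left out (10321 to 10841 with the same genes tested), and over all alternatives from 8787 with the filter of 5 CPM to 13966 with no filter on low values. The count of at least 2-fold genes ranged from 2406 to 2602 with 1 library left out (2747 to 2806 with the same genes), and over all alternatives from 2044 with the filter of 5 CPM to 3385 with a pseudocount of 0.1. The TPM table moved the median of all genes from -0.07 to -0.18, and the share of lower among called genes from 55.3% to 64.8%, which TMM scaling put at 50.3%. Of 152 called named genes, 145 were called in the same direction in every alternative that tested them, 7 lost the call in at least 1, and none that was called reversed. All alternatives tested 103 of the 152, and 99 of these kept the call. With an estimated correlation 0 lists were called, by fry 23, and with 1 library left out 9 to 13. The difference in ribosomal protein share was -0.0204 percentage points with the TPM table (exact permutation p = 0.905) and 0.150 without EndoC-BH1 libraries D and E (exact permutation p = 0.0536, fewer samples). The reason for the TPM value was not tested, nor for the reversals that follow.

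None of the lists that reversed was called by camera, and a list reversed where camera's direction turned, whatever its mean. The beta cell disallowed genes had a mean log2 fold change of -0.11 with no filter, -0.37 with TPM, -0.10 by fry, -0.18 without EndoC-BH1 A, B and C, and -0.25 to -0.011 with 1 library left out (-0.14 to -0.083, not reversed, with the same genes tested, where without A, B and C it was -0.13). The cytokine receptor list stood at -0.11 with no filter and -0.068 by fry, and the matrix list at -0.040 with no filter. The delta, gamma and epsilon list stood at 0.018 with the filter of 5 CPM, 0.052 (without EndoC-BH5 library F) to 0.51 with 1 library left out and 0.055 without A, B and C. The nuclear oxidative phosphorylation list stood at 0.00707 with quantile normalization and -0.020 without A, B and C with the same genes tested. Immediate early genes stood at -0.19 to -0.00255 with 1 library left out, reversed at -0.023 without EndoC-BH1 library D and at the upper end without E, and 0.039 without both, and glycolysis at -0.034 without both. With the same genes tested immediate early genes reversed at -0.090 without D, -0.075 without E, -0.093 without EndoC-BH5 library F and -0.020 without D and E. Higher minus lower calls reversed with quantile normalization to -5 for long intergenic and -3 for antisense RNAs. SST, not called, stood at -0.55 without A, B and C. No paired analysis was possible because the columns carry letters and not the batch numbers of the labels, and although B, C and E occur in both lines, nothing in the labels ties a letter to a batch. The planned replicate block and the planned tests on whole reads were therefore not run, the latter because too few values are whole reads. A count of 0 limits low genes to 0.0245 to 0.0367 CPM.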

Other observations

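The comparisons for one transcription unit, for the share of genes moved in a segment, for random gene sets and for the TERT segment median were chosen after the result was seen. PYY, which encodes a peptide of enteroendocrine cells, rose from 0.197 ± 0.0425 to 31.5 ± 10.5 CPM, and with NPY it was chosen after its value was seen. The counts of genes at 0 left out genes of the Y chromosome, XIST and TSIX. Few of the others were listed at 0 in every library of one line and at 5 CPM or more in the other. Besides MSN, THNSL2 was listed at 0 in all 5 EndoC-BH1 libraries and stood at 15.2 ± 4.73 CPM in EndoC-BH5, at least 426-fold higher. BCAT1 and MAGEA2B were listed at 0 in all 5 EndoC-BH5 libraries, at least 436-fold and 553-fold lower, each against a floor of 3 reads per library, and MAGEA2B has a near-identical copy, so its value is uncertain. In all, 4 genes were listed at 0 in EndoC-BH1 and at 5 CPM or more in EndoC-BH5, and 7 the other way. These genes were chosen after their values were seen.

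Higher and lower calls by biotype depended on the scaling. Of 12529 protein-coding genes 3788 were higher and 5097 lower, 4178 and 4573 with TMM scaling, 4000 and 4753 with quantile normalization and 2979 and 6070 of 12370 in the TPM table. Of 196 long intergenic RNAs 77 were higher and 50 lower, 63 and 68 with quantile normalization and 71 and 71 of 217 in the TPM table. Of 244 antisense RNAs 103 were higher and 59 lower, 81 and 84 with quantile normalization and 82 and 82 of 269 in the TPM table. The strand of counting was not given, so antisense RNAs are uncertain. Processed pseudogenes had 28 higher and 78 lower of 169, with more lower than higher in all 3 alternatives. Biotypes were looked at after the main result was seen.

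Regrouped libraries gave far fewer genes than the real grouping, but often as many lists. Of 100 splits of the 10 libraries into 5 and 5, drawn from 126 with the real one included, 1 gave as many as 10812 genes, the real one, and the highest of the others gave 1 gene. For at least 2-fold genes, 1 split gave 2776 and the highest of the others 1. For gene lists, 31 of the 100 splits gave 11 or more, the highest of the others 16. So the number of lists called by camera with a preset correlation is within what regrouped libraries give. Every other split mixes the lines unevenly. The line difference then enters the spread within groups, which keeps the gene counts small. Part of it also stays between the groups and may count among the lists, so these splits decide neither question of chance.

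Some nuclear copies of mitochondrial genes on chromosome 1 were far lower in EndoC-BH5 while most mitochondrial genes were higher. MTND1P23 fell from 637 ± 118 to 3.32 ± 0.430 CPM and MTCO1P12 from 1892 ± 209 to 131 ± 6.54 CPM, while their neighbour MTND2P28 rose from 115 ± 28.98 to 179 ± 19.4 CPM. The log2 fold changes of 6 copies spanned 9.26, where transcription of the insert as one unit would give similar changes. The highest, of MTCO2P12, came from only 1.04 ± 0.135 CPM in EndoC-BH1. The span argues against one unit only if the reads stem from the copies themselves. Over the EndoC-BH1 libraries the ratio of MTND1P23 to MT-ND1 varied by 5.28%, against 18.5% for MTND1P23 itself, so reads of the mitochondrial gene assigned to its nuclear copy are a candidate explanation. A sequence difference between the mitochondrial DNA of the lines, which could send reads to the copy in one line alone, stays open, as does a true difference between the lines.

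Fold changes shifted together over long chromosome segments. Of 270 windows of 10 Mb on the autosomes, 26 had a median fold change apart from that of all genes, 17 higher and 9 lower, at an adjusted p below 0.05, where 0.0001 is the smallest p the draws can give. In GRCh38 positions, chromosome 13 from 90000001 to 110000000 was higher by 1.36 and 1.46 on the log2 scale, and by 0.68 in the next window. Chromosome 10 was higher at both ends, by 0.56 to 0.94 in 7 windows, chromosome 7 was higher from 1 to 30000000 and lower in 6 windows of its long arm, and chromosome 18 was lower by -0.79 from 1 to 10000000. After a trend on GC content and length was removed, 25 of the 26 windows remained, which argues against GC content or transcript length bias as the whole source in these. The other, on chromosome 8 from 40000001 to 50000000, went from -0.49 (95% bootstrap interval -1.57 to -0.23, adjusted p = 0.0156) to -0.39 (-1.47 to -0.18, adjusted p = 0.0548), so that the call ended as the shift became smaller. A median of 84.5% of genes moved in the direction of their window. In 5680 random gene sets with a shift at least as large as the smallest of the 26, a comparison added after the value was seen, the median was 66.7%, as sets chosen by their median must hold a majority on that side, and 95% of them had at most 78.9%. In 17 of the 26 windows, not the same as those that were higher, the share was larger, up to 100%. In the other 9 it was not, at 65.4% to 77.1%. A median does not move with a few genes of large change. These shares therefore show how many genes moved and are no test of that explanation. In all 26 windows the genes of low and of high expression shifted the same way, where the rule fixed in advance asked for 80% and set 60% as the bound against. Of the same random sets 78.5% also shifted the same way in both parts, a smaller share than in the windows. These sets were matched only to the smallest shift of the 26, and any shift of a whole region would move both parts. So this test does not decide for or against different gene copy number of the segments in the lines. Copy number stays open, as DNA was not measured here, beside a regional difference of chromatin or of the donor cells. In the window from 140000001 to 150000000 on chromosome 5 the low genes shifted by 1.29 and the high genes by 0.08.

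TERT was tested for the shift of its chromosome segment. It lay at the 86.0 percentile of 43 genes in its 10 Mb window on chromosome 5, inside the middle 80% named in advance. The median of that window was 0.12 (95% bootstrap interval -0.18 to 0.44), far below the 1.44 of TERT, with an adjusted p of 0.382 by random draws. So a shift of the whole window is not by itself a likely source of the change. The next window, from 10000001 to 20000000, had a median of 1.16 (random draws, adjusted p = 0.00135). A shift of only a part of the segment therefore stays open. By the range named in advance alone the segment would have counted as a possible source. The comparison with the segment median, which turned that verdict for the window as a whole, was added after the percentile was seen.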
